A study of Mus musculus with 3 samples.

How the data were processed

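Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in C2C12 cells, an established mouse myoblast line, kept in the proliferating state. One library was made with a rabbit antibody against KAP1 and one with an antibody against H3K9me3, the trimethylated form of lysine 9 of histone H3. Another library, made with no antibody, has no peak list analysed here. Cells were counted, fixed with formaldehyde, lysed and sonicated before library preparation, per the labels' protocols. There was 1 library per antibody and therefore no replicate, so no value below carries a spread between replicates.

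Bowtie2 2.2.1 and the mouse genome build mm9 are named in the submitters' processing notes. Each deposited list gives a chromosome, a start, an end, a name and a score for every region. In the KAP1 list the score that the authors deposited is a number with decimals, no lower than 70, and the peaks carry names of the form written by the MACS peak caller. In the H3K9me3 list the deposited score is a whole number from 11 to 4360, and it follows the width of the region closely (Spearman's rho of 0.987 across regions). What either score measures, the caller of the H3K9me3 list, the caller settings and the use of the no-antibody library as control are not given in the sources used here. Scores were used only to describe, rank, filter and compare regions within their own list. The numbers in the names run to 36417 in the KAP1 list of 19549 peaks and to 46867 in the H3K9me3 list of 39526 regions, so each list is a subset of the numbered calls. Total read counts per library are not given in the sources used here, so the depth is unknown and no detection limit from depth can be set. Intervals below cover counting error over regions only. Neighbouring regions are not independent of one another.

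Both lists cover chromosomes 1 to 19, X and Y. Their last base on chromosome 7, at 152408565, lies beyond the last gene of that chromosome in the GRCm38.p6 gene table, so that table was not used with these positions. No genome sequence or gene annotation of mm9 was used here. The planned comparisons of promoters, exons and introns, of gene lists (muscle, imprinted, zinc finger, protocadherin, olfactory, vomeronasal, ribosomal, cell division, germline, heterochromatin machinery and other lineages) and of peak sequence were therefore not run, and regions are named by position. Positions are in mm9, counted from 1.

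Regions overlapped when they shared at least 1 bp. Observed overlap was set against 1000 random placements of the KAP1 peaks on their own chromosomes. Widths were kept, and placements fell between the first and last base that either list covers on a chromosome. Assembly gaps inside those bounds, and sequence where reads cannot be placed uniquely, were not excluded. The rank of the observed value among the placements describes these lists and is not a test between conditions. Lists of 19549 peaks were simulated with 20% or 40% of the peaks planted in H3K9me3 regions. The planted share recovered was 19.8% and 39.6%, and with 0% planted it was 0.0513%. It was computed as the excess over placement divided by the share of placed peaks without overlap, which is not the fold over placement given below. The unplanted peaks were placed in the same random way, so the simulation checks the computation only. It does not show whether random placement is a fair baseline for KAP1 peaks, which cluster.

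KAP1 peaks that overlapped H3K9me3 were compared with the others by the difference of medians and a two-sided permutation of the overlap over peaks, with 100000 resamples. Score and width were the 2 comparisons of that family, and Benjamini-Hochberg adjustment left both p-values as they were. Deciles were made by score or width within a list. Intervals of shares are 95% Wilson intervals and intervals of densities are exact 95% Poisson intervals. Density was taken over the span between the first and last covered base of a chromosome. Windows were 1 Mb wide and regions were assigned to them by midpoint. Correlations over windows were set against 100 shifts of the KAP1 counts along each chromosome.

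By a rule fixed before the data were examined, the 5 highest-scoring regions are named in each of 3 classes: KAP1 peaks that overlap H3K9me3, KAP1 peaks with no H3K9me3 region within 10 kb, and H3K9me3 regions. Ties were broken by width and then by position. The top 1% of KAP1 peaks as a class, and windows, chromosomes and clusters named beyond these, were chosen after their values were seen. The alternatives fixed beforehand were other overlap limits, the upper 50% of each list by score, a circular shift in place of random placement, the list without its 1% highest scores, autosomes alone, merged regions, smaller windows and windows without the densest. Clusters of KAP1 peaks were added after the data were seen. They were made by chaining peaks no more than 10 kb apart. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.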

Results

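KAP1 (TRIM28) is a corepressor that KRAB zinc finger proteins bring to DNA, and its partner SETDB1 is a histone methyltransferase that makes H3K9me3. The study mapped both in proliferating C2C12 myoblasts, the state before muscle differentiation. The KAP1 list held 19549 peaks that covered 14.8 Mb, with a median width of 651 bp (interquartile range 530 to 843). The H3K9me3 list held 39526 regions that covered 39.7 Mb, with a median width of 607 bp (interquartile range 323 to 1148). The widest KAP1 peak spanned 11155 bp and the widest H3K9me3 region 36277 bp. Each list came from 1 library, and the read depth of neither is known.

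The first comparison asked how far KAP1 sites in myoblasts coincide with H3K9me3. Of the 19549 KAP1 peaks, 8623 (44.1%, interval 43.4 to 44.8) overlapped an H3K9me3 region. Random placement gave 2.71% on average and at most 3.06%, so the observed share was 16.2-fold higher and none of 1000 placements reached it. Sites also enriched in the no-antibody library could enter both lists and count as overlap, which was not checked. Within 1 kb of an H3K9me3 region lay 50.4% of KAP1 peaks, against 5.35% placed, and within 10 kb 66.0%, against 23.4% placed. The 10926 KAP1 peaks without overlap lay a median of 18.1 kb from the nearest H3K9me3 region. Seen from the other list, 6101 of the 39526 H3K9me3 regions (15.4%, interval 15.1 to 15.8) held a KAP1 peak, 11.4-fold more than the 1.35% of random placement. Of those 6101 regions, 4437 held 1 KAP1 peak and 1664 (27.3%) held more, up to 7.

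KAP1 peaks with H3K9me3 scored higher and were wider than KAP1 peaks without it. The median score was 135.0 (interquartile range 93.6 to 221.1) with H3K9me3 and 95 (80.1 to 127.4) without. The difference of 39.995 exceeded that of all 100000 permutations of the overlap over peaks (permutation test, two-sided, p = 1e-05, the smallest they can give, adjusted p = 1e-05). The median width was 732 bp with H3K9me3 and 602 bp without, a difference of 130 bp (permutation test, two-sided, p = 1e-05, again the smallest possible, adjusted p = 1e-05). These tests run over peaks of a single library, which are not replicates. When scores were instead rotated along the genome so that neighbours stayed together, p was 5.1e-05 for score and for width in a permutation test over rotations, the smallest that 19549 peaks allow. Neither test allows for wider peaks overlapping more often under random placement. The placed share was 2.38% in the lowest score decile (median width 509 bp) and 3.43% in the highest (1083 bp). Width also followed score in this list (Spearman's rho of 0.640), so the differences in score and width are not independent.

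The share of KAP1 peaks with H3K9me3 rose with the KAP1 score through most of the list and was low in the top 1%. It was 25.8% (interval 24.0 to 27.8) in the lowest decile, 41.8% in the sixth and 72.3% (interval 70.3 to 74.3) in the ninth. In the highest decile it was 63.3% (interval 61.1 to 65.4), and 69.7% (interval 67.5 to 71.8) without the top 1% of the list, a value added after the data were seen. Random placement gave between 2.38% and 3.43% across the deciles. In the top 1% of the list, 195 peaks with a score of at least 2144, 11 peaks overlapped H3K9me3. That share of 5.64% (interval 3.18 to 9.82) was within the range of random placement, whose mean was 3.48% and highest value 7.18%. In the other 19354 peaks the share was 44.5% (interval 43.8 to 45.2). When at least 50% of the peak had to be covered, 1 of the 195 met the limit. The share was also low at a wider cut. Among the 323 peaks with a score above 1000, 25 overlapped H3K9me3 (7.74%, interval 5.30 to 11.2). Those 323 include the 195 peaks and their 11 overlaps, so the values are not independent.

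**Figure D1:**
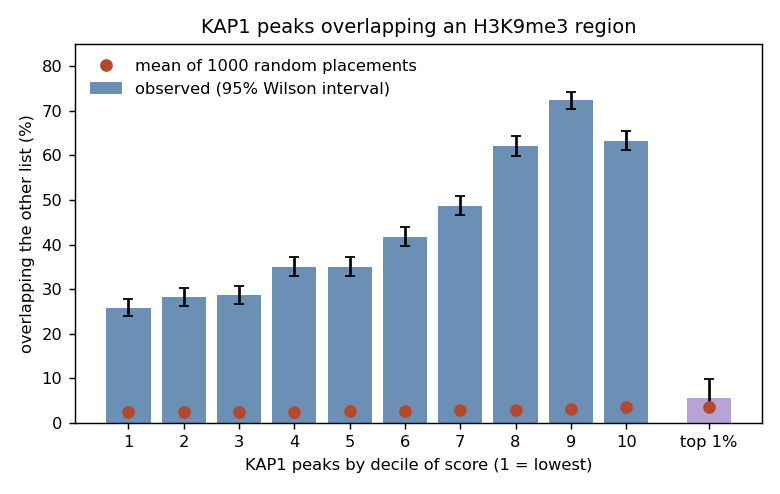
Share of KAP1 peaks that overlap an H3K9me3 region (y axis, percent) by decile of KAP1 score (x axis, 1 the lowest) and for the 195 peaks of the top 1%; bars are observed shares with 95% Wilson intervals and dots are the mean of 1000 random placements. The share climbs to 72.3% in the ninth decile and is 5.64% in the top 1%.

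The top 1% of KAP1 peaks were concentrated in a few places. The 1 Mb window from 126 to 127 Mb on chromosome 8 held 32 of the 195, and the window from 47 to 48 Mb on chromosome 6 held 17. Another 32 lay in the windows from 21 to 24 Mb on chromosome 13, with 10, 8 and 14 of them per window in order of position, none of which overlapped H3K9me3. These windows together held 81 of the 195 peaks (41.5%). At the first covered bases of chromosome 9, from 3.00 Mb, a further 7 lay in a single cluster of 15 peaks, and no H3K9me3 region lay in that cluster. Within the chromosome 8 window, 54 KAP1 peaks stood in 86.0 kb between 126061992 and 126148013, with a median score of 2761, and 5 of them overlapped H3K9me3. Scores in this part of the list are limited in their use for ranking, since 99 peaks have a score of exactly 3100 and 8 have a higher one.

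**Figure D2:**
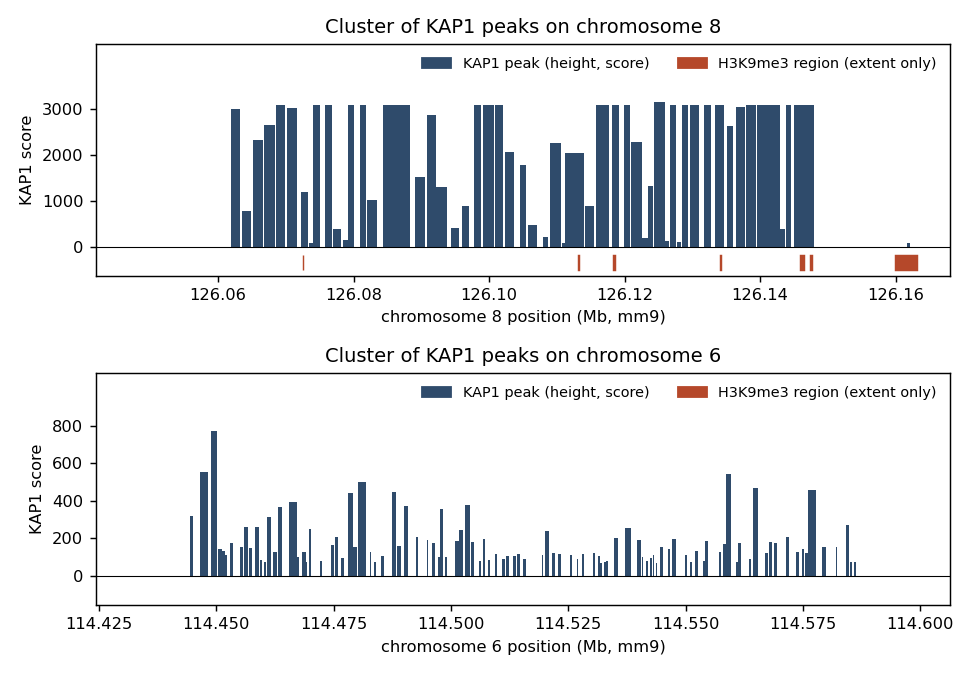
KAP1 peaks (blue bars, width to scale, height the KAP1 score) and H3K9me3 regions (red blocks, extent only, outlined so that the narrowest stay visible) in clusters on chromosome 8 and chromosome 6; x axes are mm9 positions in Mb. The chromosome 8 cluster holds 54 peaks with a median score of 2761 and narrow H3K9me3 regions; the chromosome 6 cluster holds 101 peaks with a median score of 133.5 and no H3K9me3 region.

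Among KAP1 peaks with H3K9me3, the 5 ranked first all had a score of 3100, so their order was set by width. Those on chromosome 6 were at 47629791 to 47637062, 47603843 to 47608155 and 47697358 to 47701492. The others were on chromosome 1 at 172993800 to 172997619 and on chromosome 8 at 126144955 to 126148013. By their score all 5 belong to the top 1% of the list. There 11 of 195 peaks overlapped H3K9me3, a share within the range of random placement. Only 1 of those 195 had at least 50% of its length covered, so no more than 1 of these 5 did. Their rank therefore reflects the KAP1 score and width, not the extent of H3K9me3. Among the 6645 KAP1 peaks with no H3K9me3 region within 10 kb, the first was on chromosome 19 at 5037850 to 5038790, with a score of 3199 and 28.1 kb to the nearest H3K9me3 region. The next were on chromosome 13 at 22113885 to 22114634 (score 3177), chromosome 1 at 167571515 to 167572066 (score 3176), chromosome 6 at 38483590 to 38484398 (score 3172) and chromosome 2 at 118872048 to 118872715 (score 3106).

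The widest H3K9me3 regions held KAP1 most often. In the narrowest decile, regions of up to 185 bp, 6.10% (interval 5.39 to 6.89) held a KAP1 peak. The share was 4.73% (interval 4.11 to 5.44) in the next decile and 5.79% in the one after, and it was higher in each wider decile from there. In the widest, regions of 2193 bp and more, 61.3% (interval 59.8 to 62.8) did. Wider regions are also hit more often by chance, at 3.60% in the widest decile and 0.677% in the narrowest. The ratio of observed to placed was 17.0 in the widest decile and 9.01 in the narrowest, with values from 6.26 to 13.5 between them. By decile of H3K9me3 score the share was 4.93% in the lowest and 62.1% in the highest. Score followed width closely in this list, so the trend cannot be assigned to width rather than score.

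**Figure D3:**
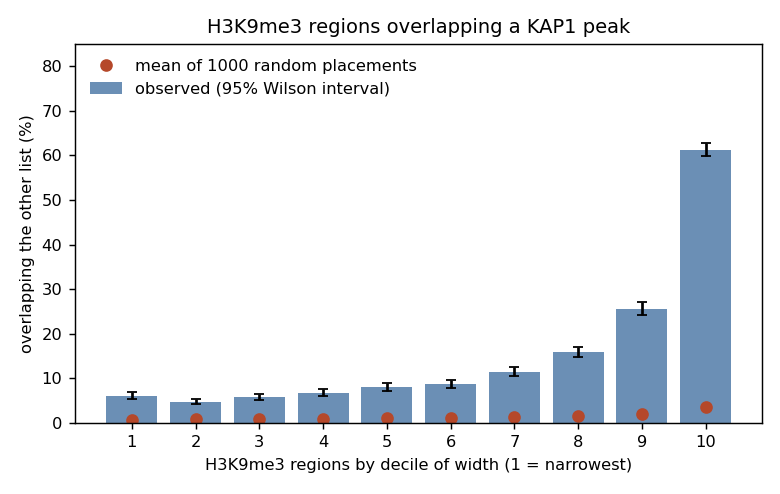
Share of H3K9me3 regions that overlap a KAP1 peak (y axis, percent) by decile of region width (x axis, 1 the narrowest); bars are observed shares with 95% Wilson intervals and dots are the mean of 1000 random placements. The share is 61.3% in the widest decile and below 26% in each of the others.

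The 5 highest-scoring H3K9me3 regions lay on chromosomes 7, 10 and 17. They were broad, which follows from how closely score tracked width in this list (Spearman's rho of 0.987). The first spanned 36277 bp on chromosome 7, from 30916826 to 30953102, with a score of 4360. It was followed by chromosome 10 at 81560488 to 81583468 (score 3223) and chromosome 17 at 22419920 to 22443391 (score 2903). The next were chromosome 17 at 17270764 to 17289868 (score 2652) and chromosome 10 at 81512126 to 81530529 (score 2586). The regions on chromosome 17 at 22419920 and on chromosome 10 at 81512126 lay 58.3 kb and 35.4 kb from the nearest KAP1 peak, and the others held one.

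Regional density was compared next. Over 2593 windows of 1 Mb, counts of the 2 lists correlated with a Spearman's rho of 0.467 (Pearson's r of 0.336), above the highest rho of 0.103 among 100 shifts along the chromosomes. Windows are not replicates. The densest windows differed between the lists. For H3K9me3 they were 66 to 67 Mb on chromosome 13 with 193 regions, 19 to 20 Mb on chromosome 12 with 163, and 65 to 66 Mb on chromosome 13 with 146, against a median of 13. By covered length, 81 to 82 Mb on chromosome 10 led with 263.6 kb, followed by 22 to 23 Mb on chromosome 17 with 261.4 kb. For KAP1 the densest were 114 to 115 Mb on chromosome 6 with 106 peaks, 23 to 24 Mb on chromosome 13 with 60, and 126 to 127 Mb on chromosome 8 with 59, against a median of 7. The same 3 windows held 8, 17 and 12 H3K9me3 regions. The window with the most overlapping KAP1 peaks was 8 to 9 Mb on chromosome 7, where 19 of 20 KAP1 peaks overlapped H3K9me3. In the window of chromosome 13 with the most H3K9me3 regions, 17 of 29 KAP1 peaks did.

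Chromosome 15 had the highest density of both lists. It held 11.9 KAP1 peaks per Mb (interval 11.2 to 12.5), 1.56-fold the 7.57 of all chromosomes. It held 29.3 H3K9me3 regions per Mb (interval 28.2 to 30.3), 1.91-fold the 15.3 of all chromosomes. The excess was mostly in regions not shared by the lists. KAP1 peaks without H3K9me3 were 1.93-fold denser on chromosome 15 than over all chromosomes (interval 1.80 to 2.06), and those with H3K9me3 1.11-fold (interval 0.998 to 1.23). For H3K9me3 regions the ratios were 2.05 without KAP1 (interval 1.97 to 2.13) and 1.17 with it (interval 1.04 to 1.32). Accordingly 31.2% (interval 28.7 to 33.9) of the KAP1 peaks of chromosome 15 overlapped H3K9me3, 6.13-fold over placement, while on chromosome 16 the share was 51.8% and 23.3-fold over placement. Chromosome 13 came second in H3K9me3 density, with a ratio of 1.33, and had a KAP1 ratio of 1.18. Chromosome 7 had the lowest H3K9me3 ratio of the autosomes, 0.711 (interval 0.676 to 0.746), and a KAP1 ratio of 0.892. The X chromosome stood at 1.09 for KAP1 (interval 1.03 to 1.15) and 1.03 for H3K9me3 (interval 0.989 to 1.07). In the upper 50% of each list by score the X ratios were 0.959 (interval 0.883 to 1.04) and 0.882 (interval 0.831 to 0.935), so the ratio for X depends on the scores included. The interval includes 1 for KAP1 in the upper 50% and for H3K9me3 in the full list, so a reversal of direction is not shown.

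**Figure D4:**
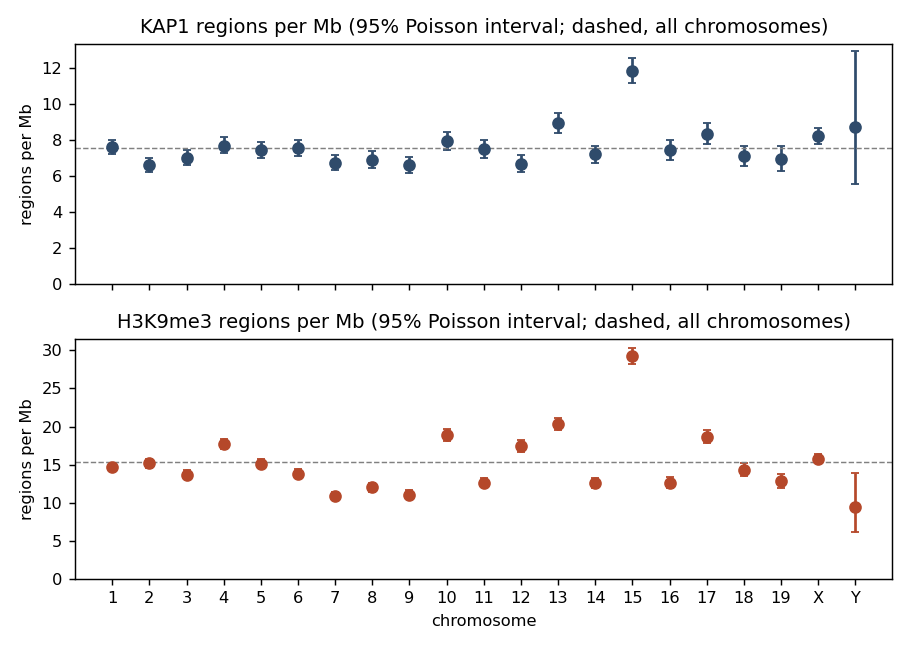
Regions per Mb (y axes) on each chromosome (x axis) for the KAP1 list, above, and the H3K9me3 list, below; points carry exact 95% Poisson intervals and the dashed line is the density over all chromosomes. Chromosome 15 stands highest in both lists, at 11.9 KAP1 peaks and 29.3 H3K9me3 regions per Mb.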

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

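The overlap of the lists exceeded random placement under every alternative run, from 9.41-fold to 25.5-fold for KAP1 peaks and from 6.76-fold to 17.3-fold for H3K9me3 regions. The shares themselves moved with the definition. With at least 50% of the KAP1 peak covered they were 37.9% of KAP1 peaks and 12.8% of H3K9me3 regions, and within 1 kb 50.4% and 19.5%. In the upper 50% of KAP1 peaks by score they were 57.7% and 10.5%, and against the upper 50% of H3K9me3 regions 38.4% and 25.0%. A circular shift in place of random placement raised the fold for H3K9me3 regions to 12.3. Without KAP1 clusters of 10 or more peaks, an alternative added after the data were seen, 45.0% of KAP1 peaks overlapped. For the top 1% by score, likewise added, the share was 1.68% without those clusters, 0.513% with 50% of the peak covered and 10.3% within 1 kb, each below the 38.3% or more of the other peaks. In the upper 50% by score, the density ratio of chromosome 15 for H3K9me3 was 2.12 and the X ratios were 0.959 for KAP1 and 0.882 for H3K9me3. In windows of 100 kb Spearman's rho was 0.369. The cause of these shifts was not tested beyond what each definition removes. Merging regions within 1 kb left 16288 KAP1 and 34656 H3K9me3 regions. These counts are among 28 further values that stayed within 1.5 times the count, within the interval of the value or on the same side of the test's threshold. Not all of the 28 could have moved. A circular shift leaves the observed shares as they are, and leaving out 1% of the KAP1 peaks can hardly change their share. The number 28 is therefore no measure of robustness. No paired analysis was possible because there is 1 library per antibody, and no replicate could be left out for that reason. The planned promoter, gene list and sequence alternatives were not run, since no mm9 annotation or sequence was used here. Unknown read depth limits what the absence of a region from a list can show.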

Other observations

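The tests in this part were chosen after the data were seen, except the chromosome 15 ratio in the upper 50% by score, an alternative fixed beforehand whose reading as a test came after. The overlap with H3K9me3 differed with how closely KAP1 peaks stood together. Peaks with no other peak within 10 kb numbered 8945, and 25.9% of them (interval 25.0 to 26.8) overlapped H3K9me3. The 10140 peaks in groups of 2 to 9 overlapped in 61.8% (interval 60.9 to 62.8). The 464 peaks in the 24 clusters of 10 or more overlapped in 7.76% (interval 5.66 to 10.6), and in 11 of those clusters no peak did. Groups of 2 to 9 scored higher than single peaks, with medians of 121.0 and 95, but within each of the 10 score deciles their share was higher, by 18.0 to 39.5 percentage points. Peaks of a group were counted separately. Since 1664 H3K9me3 regions held more than 1 KAP1 peak, these shares and intervals are not over independent units. In H3K9me3 regions of 3 kb or more, 46.7% of 3658 KAP1 midpoints (interval 45.1 to 48.3) fell in the outer 20% at either end, against 39.9% on average for random placement. Single placements put few midpoints in such regions and reached up to 56.4%.

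The KAP1 peaks of the top 1% by score seldom overlapped H3K9me3. The share was 5.64%, against 44.5% in the rest of the list. A few dense clusters do not carry the pattern, since with 1 peak counted per cluster the share was 3.96% (interval 1.55 to 9.74). It stays open whether these sites are also enriched in the library without antibody, which is not analysed here. Binding of KAP1 without H3K9me3 is a hypothesis that the lists alone cannot separate from that; no biological explanation was tested, since the design gives no group for one.

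Chromosome 15 held more calls per Mb in both lists. The weakest calls are not the source, since the KAP1 ratio in the upper 50% by score was 1.65 (interval 1.52 to 1.78). A few dense windows are not either, because the median 1 Mb window of chromosome 15 held 1.57 times the KAP1 peaks of the median window overall (bootstrap interval 1.29 to 1.71). The excess therefore ran along much of the chromosome and lay mostly in unshared regions. Extra copies of chromosome 15 in these cells may be a cause, and the read coverage of the no-antibody library that would test it is not analysed here; no biological explanation was tested.

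A cluster of 101 KAP1 peaks filled 142.0 kb on chromosome 6, from 114444370 to 114586342, where the density of the whole list would give 1.08. Of its peaks, 71.3% (interval 61.8 to 79.2) scored above the median of the list, so they were not mainly the weakest calls. That median, 106.1, is itself close to the lowest score of 70. The cluster had a median score of 133.5 and a highest of 772, so calls near the score limit are not excluded. Calls were not raised in both lists alike. The cluster held 0 H3K9me3 regions, and the 3 that a count of 0 allows are at most 1.38 times the 2.17 of that list's density. KAP1 stood at 93.9 times its own. The caller of the H3K9me3 list and the use of a control are unknown, and few regions were expected. The count of 0 therefore does not decide whether the interval has extra DNA copies. Copies that raised KAP1 calls alone, DNA present in the KAP1 library alone, or KAP1 spread over this interval may be the source and stay open; no biological explanation was tested.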
